A study of Mus musculus with 20 samples.

How the data were processed

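Liver RNA from 20 male CD-1 mice, an outbred stock, was measured on Affymetrix 3' expression arrays after labelling with biotin. The mice had received phenobarbital sodium at 80 mg/kg/day, or the methylcellulose vehicle alone, by mouth once a day for 28 or 90 days. Each of the 4 groups held 5 mice, each mouse gave 1 array, and tissue was taken from the left lateral lobe on the day after the last dose. Phenobarbital (PB below, with CMC for the vehicle) is a sedative drug and the classical activator of the constitutive androstane receptor in hepatocytes, which raises enzymes of drug metabolism. The group and the replicate number of each array were read from the sample titles, with 0 columns left unused.

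The deposited table held log2 signal intensities made by the authors with RMA, per the submitters' processing notes; RMA corrects background, equalises the distributions of the arrays and combines the probes of each probe set. Its version and the genome build were not given in the sources used here. The values were used as deposited, with no further transformation. RMA compresses differences near background and near saturation, so that fold changes of very dim and very bright probe sets can come out too small. The table held 45037 probe sets, of which 34945 were listed with 1 gene symbol in the platform annotation of 2016, 932 with several and 9160 with none. The Entrez identifiers of 34741 of these probe sets were found in the reference annotation, 204 were not, and 0 symbols were changed. Where a gene had several probe sets, the one with the highest mean over the 20 arrays stood for it, which gave 18193 genes. A gene was kept when it exceeded the array's own 25th percentile, between 3.96 and 4.26, on at least 5 arrays, which left 16054 genes and removed 2139. Por and other genes without a probe set in the table were not analysed here. Arrays give no counts, so their number limits the precision.

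A linear model with 1 mean per group was fitted to all 4 groups together in limma 3.58.1 under R 4.3.3, with an intensity trend in the variance prior and 16 residual degrees of freedom. The contrasts were PB against CMC at 28 days, PB against CMC at 90 days, the difference between these effects, and CMC at 90 against 28 days. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Changes are PB minus CMC in log2 units with the standard error of the model, and group values are means ± SD with n = 5. All tests were two-sided. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

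The genes named were set by a rule written before the data were examined. It took, at each duration, the 8 called genes with the largest increase and the 8 with the largest decrease whose arrays did not overlap between groups, and for each gene list up to 2 called members (1 for marker lists) with the largest change. It took always Cyp2b10, Cyp2c55, Cyp3a11, Por, Alas1, Gadd45b, Nr1i3, Meg3, Mki67, Ccnd1, Glul and Cyp7a1. For the difference between durations it took the 6 called genes with the smallest p, or the 3 genes with the smallest p if fewer than 3 were called, and for the vehicle groups the 5 largest changes in each direction. Other members of lists, and the remaining genes called at 90 days, were chosen as examples after their values were seen.

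A total of 34 gene lists with 948 entries, of which 846 were measured and 827 tested, was also fixed beforehand. They covered enzymes of drug metabolism, pathways of lipid, glucose, bile acid and heme metabolism, stress responses, proliferation, sex-biased and zonated liver genes, and markers of the other cell types a liver sample could hold. Each list was tested with limma's camera at a preset correlation between genes of 0.01, which asks whether its members rank above or below the other genes, with adjustment over the 34 lists. The test was repeated with the correlation estimated from the data, and members were also counted with p-values adjusted over the list alone.

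The alternatives planned were no filter, a filter at the 50th percentile, the mean of all probe sets of a gene, all probe sets tested singly, no probe sets of the _x_at or _s_at kind, a variance prior without trend, a fit of only the groups compared, array weights, centring on the 75th percentile, cyclic loess, the replicate number as a block and the removal of each array in turn. A few more were added after the data were seen: removal of the 2 arrays that stood apart together, the first principal component as a covariate, the same covariate with an estimated correlation, and lists without the genes called singly at either duration. A planned comparison of the 3' and 5' control probe sets was not run, because the table used held 0 control probe sets.

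The model was tested on simulated data, in which the residuals of the 20 arrays were dealt out at random and 200 of 16054 genes were changed, in 5 runs. A change of 1 log2 unit was recovered for 72.8% of genes in the groups of 28 days and for 71.6% in those of 90 days, and a change of 2 log2 units for 95.2% and 97% of genes. On average 6.2 and 0.4 unchanged genes per run were called. Residuals were dealt out over all groups, so these figures do not describe the real groups of 28 and 90 days. With 200 changed genes the adjustment is also milder than with the 8 and 23 genes called in the real data. Recovery there may thus be lower. Of random lists of 30 genes, 100 of 100 moved by 0.5 log2 units were found and 0 of 100 unmoved ones were called; random lists lack the shared variation of a real pathway, so this says nothing on false calls of real lists. No 2 arrays were copies of each other: the correlation of array pairs lay between 0.882 and 0.993. The labels give no array or hybridisation batch, and the vehicle groups of the 2 durations were separate animals, so that duration cannot be told apart from age or from any batch that followed it.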

Results

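The data were 20 array profiles of mouse liver RNA, with 5 vehicle and 5 phenobarbital mice at each of 2 durations of daily dosing, 28 and 90 days. The design asks which liver transcripts differ between phenobarbital-treated and vehicle-treated males after 4 weeks and after about 3 months, and whether the response differs between these times. Values are log2 RMA intensities, and n = 5 mice per group throughout. The mice were separate animals, so the p-values measure the spread between mice. The first principal component held 55.6% of the variance, and 2 phenobarbital arrays lay at its low end: replicate 5 at 28 days with a score of -107.9 and replicate 3 at 90 days with -65.2, against -39.8 for the next array. Group means of this score did not differ between treatments by exact permutation tests (p = 0.786 at 28 days, p = 0.262 at 90 days, n = 5 per group), although the spread was wide.

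After 28 days, phenobarbital raised the transcripts of Cyp2b10 and of several Cyp2c genes, which encode cytochrome P450 enzymes that oxidise drugs and steroids. Cyp2c55 rose 40.9-fold (5.35 ± 0.30 log2 units, adjusted p = 1.15e-09), from 6.22 ± 0.61 in vehicle livers to 11.57 ± 0.48. Cyp2b10, the standard target of the constitutive androstane receptor in the mouse, rose 29.8-fold (4.90 ± 0.62, adjusted p = 0.000572). Cyp2c37, Cyp2c54 and Cyp2c50 rose by 2.20 ± 0.30, 2.05 ± 0.22 and 1.22 ± 0.20 log2 units. Ces2a, a carboxylesterase that cleaves ester drugs and lipids, rose 2.34-fold (1.22 ± 0.10, adjusted p = 4.49e-07), and Nebl, which encodes the actin-binding protein nebulette, rose by 2.41 ± 0.42 (adjusted p = 0.024). Its vehicle level lay 0.21 log2 units above background, taken as the 25th percentile of each array, so the size of this change is not exact and may be too small.

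These 7 genes and the uncharacterised 4931406C07Rik (0.95 ± 0.14) were the 8 genes called among 16054, all 8 of them higher under phenobarbital, and in each of them the 5 treated livers lay above the 5 vehicle livers. Over all genes the groups did not overlap for 87 (0.542%), where chance gives 0.794%. At an unadjusted p under 0.05 there were 459 genes, where 803 would be expected by chance. All 3 probe sets of Cyp2b10 were called, with changes from 3.71 to 5.05 log2 units. The lowest came from the probe set that was not of the _s_at kind. Of 3 probe sets of Nebl only 1 was called, and with the mean of its probe sets Nebl gave 0.81 log2 units (adjusted p = 0.135). In a fit of the 28-day groups alone 4 genes were called, and Nebl (adjusted p = 0.493), Cyp2c50 (0.19), 4931406C07Rik (0.0742) and Cyp2c37 (0.0648) were not. The call of Nebl was also lost without vehicle replicate 1, 2, 4 or 5 or treated replicate 1 or 3 (adjusted p between 0.0503 and 0.12), and that of Cyp2c50 without treated replicate 1 (0.0501) and with the replicate block (0.0741). With the 2 arrays at the end of the first component left out 11 genes were called, and 17 with that component as a covariate, the 8 above among them in each case.

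Several further genes had large mean differences at 28 days without being called. The oestrogen sulfotransferase Sult1e1 was higher by 1.90 ± 0.36 log2 units (adjusted p = 0.0641), and it was called without treated replicate 4 (2.31, adjusted p = 0.000242). Cyp2b13, a P450 expressed mainly in females, was higher by 2.54 ± 0.57 (adjusted p = 0.248), and by 3.04 without treated replicate 5 (0.0164). S100a8, a calcium-binding protein of myeloid cells, was higher by 5.06 ± 1.13 (adjusted p = 0.248), and by 5.95 without treated replicate 5 (0.0323). Cyp2c65 gave 1.76 ± 0.35 (adjusted p = 0.0902) and was called without treated replicate 3 (2.02, 0.0196). In vehicle livers Cyp2c65 lay 0.33 log2 units below background and Sult1e1 0.05 above it, so the sizes of their changes are not exact. Orm3, an acute-phase glycoprotein, gave 1.19 ± 0.32 (0.715) and was called without vehicle replicate 5 (1.54, 0.0137). Only 1 of 5 treated livers lay above all vehicle livers for Orm3. Each of the genes in this paragraph was called in only 1 of 10 removals of a single array. In other removals the adjusted p reached 0.262 for Sult1e1, 0.735 for Cyp2b13, 0.644 for S100a8 and 0.349 for Cyp2c65.

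**Figure D1:**
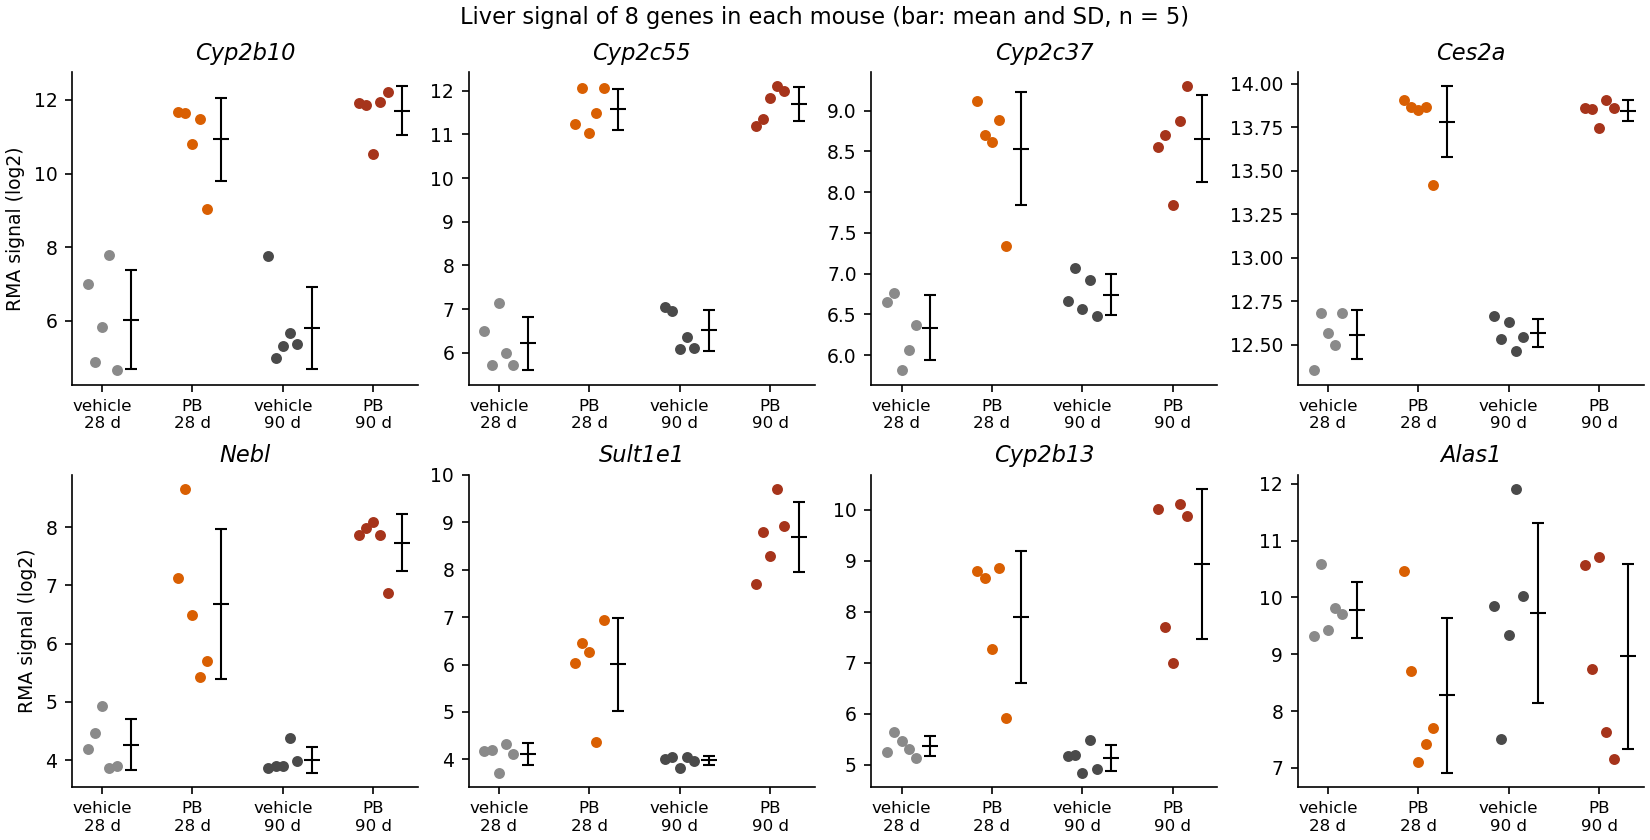
RMA signal on the log2 scale (vertical axes, which differ between panels and do not start at 0) of 8 genes in each of the 20 mice, by treatment and duration; points are mice and bars are the mean and SD of 5. The 5 treated livers lie above the 5 vehicle livers for Cyp2b10, Cyp2c55, Cyp2c37, Ces2a, Nebl, Sult1e1 and Cyp2b13 at both durations, and the groups overlap for Alas1.

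Among the drug-metabolising groups at 28 days, the list of 36 tested genes, P450 enzymes of families 1 to 3 with cytochrome b5 and its reductase, ranked above other genes (adjusted p = 4.31e-12, and adjusted p = 0.0248 with an estimated correlation). Of these, 22 had positive changes, 5 were called over all genes and 10 when adjusted over the list alone. Their median change was 0.08 log2 units, and without the genes called singly at either duration the other 29 were not called (adjusted p = 0.116). The 44 genes of conjugation and epoxide hydrolysis also ranked higher (adjusted p = 1.63e-05), with 8 higher at an unadjusted p under 0.05 in limma, 0 called over all genes and 5 adjusted over the list alone: Sult1e1, Sult1c2, Gstt3, Gstt1 and Gsta2. Their call did not hold with an estimated correlation (adjusted p = 0.0918 with an estimated correlation). Without Sult1e1 the other 43 still ranked higher (adjusted p = 0.000253, and 0.281 with an estimated correlation). The 41 esterases, aldehyde dehydrogenases, reductases and other oxidases (below, esterases and reductases) ranked higher (adjusted p = 0.0119; adjusted p = 0.401 with an estimated correlation), with Ces2a the 1 member called over all genes and adjusted over the list alone; without Ces2a the list gave 0.116.

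A list of 28 genes tied to liver tumours and the fetal liver ranked higher at 28 days (adjusted p = 1.02e-05, and adjusted p = 0.00191 with an estimated correlation). The members called over all genes were 2, Cyp2b10 and Cyp2c55, both enzymes of drug metabolism, and 3 were called adjusted over the list alone, with the drug exporter Abcc4 (1.02 ± 0.27). Without these 3 genes the list was not called (adjusted p = 0.116). Genes expressed more in female than in male livers ranked higher in these males, with 26 of 31 positive and a median of 0.38 log2 units (adjusted p = 2.07e-09; adjusted p = 0.0758 with an estimated correlation). Limma gave 6 higher at an unadjusted p under 0.05, 0 called over all genes and 5 adjusted over the list alone, among them Sult1e1, Cyp2b13, Cyp2b9 (2.75) and Gstt3 (1.49). Without Sult1e1 and Cyp2b13 the other 29 still ranked higher (adjusted p = 1.77e-06, and 0.244 with an estimated correlation). The 32 genes expressed more in males were not called (median -0.08, adjusted p = 0.1).

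Sterol and protein-folding genes lay lower at 28 days as groups, without a single member called. Of 26 genes of cholesterol synthesis, uptake and regulation 2 had positive changes, and the median was -0.33 log2 units (adjusted p = 4.31e-12; adjusted p = 0.0758 with an estimated correlation). Squalene epoxidase Sqle gave -0.96, Lss -0.83, Fdps -0.81 and Hmgcs1 -0.61. Of 36 genes of endoplasmic reticulum stress and heat shock 3 were positive, with a median of -0.35 (adjusted p = 1.69e-07; adjusted p = 0.401 with an estimated correlation), among them Creld2 at -1.27, Syvn1 at -0.89 and Hyou1 at -0.85. The 17 genes of heme synthesis, transport and breakdown ranked lower, with 2 positive (adjusted p = 0.0411; adjusted p = 0.0918 with an estimated correlation), and the 35 lipogenic genes did too (median -0.12, adjusted p = 0.0411; adjusted p = 0.787 with an estimated correlation). The lipogenic list turned to a positive median of 0.09 (adjusted p = 0.498) without the 2 arrays at the end of the first component, and the heme list was not called (0.0781). Limma called 0 members of these 4 lists over all genes and 0 adjusted over the list alone, while 10, 1, 1 and 2 members in the order given were lower at an unadjusted p under 0.05.

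Markers of other cell types were recorded beside these groups. The neutrophil list ranked higher at 28 days (13 genes, median 0.20, adjusted p = 0.000197, and adjusted p = 0.0758 with an estimated correlation). S100a8 was the 1 member called adjusted over the list alone, with 0 called over all genes by limma and 3 higher at an unadjusted p under 0.05. Without S100a8 the other 12 genes still ranked higher (median 0.18, adjusted p = 0.0079, and 0.302 with an estimated correlation). Markers of lymphocytes and antigen presentation also did (22 genes, median 0.18, adjusted p = 0.000851; adjusted p = 0.533 with an estimated correlation), but not without the 2 arrays (median 0.01, 0.838), and the 54 proliferation genes had a median of 0.06 (adjusted p = 0.0411; 0.697 with an estimated correlation) and of 0.00 without the 2 arrays (0.987). In all, 12 of 34 lists were called at 28 days, 2 with an estimated correlation. Of 100 splits of these 10 arrays into groups of 5, the real one included, 57 called at least as many lists.

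After 90 days, the same P450 genes were raised and further genes joined the list. Cyp2b10 rose 59.1-fold (5.88 ± 0.62 log2 units, adjusted p = 2.79e-05) and Cyp2c55 36.3-fold (5.18 ± 0.30, adjusted p = 2.16e-09). The Cyp2b10 probe set that was not of the _s_at kind gave a smaller change, 4.62 log2 units. Sult1e1, which inactivates oestrogens by adding sulfate, rose by 4.71 ± 0.36 log2 units (adjusted p = 1.44e-07), from 3.98 ± 0.09 to 8.69 ± 0.75, and Nebl by 3.73 ± 0.42 (adjusted p = 5.38e-05). Cyp2b13 rose 14.1-fold (3.82 ± 0.57, adjusted p = 0.00211) and the protease inhibitor gene Serpinb1a 7.26-fold (2.86 ± 0.49, adjusted p = 0.0106). Cyp2c65 and Orm3 rose by 2.63 ± 0.35 and 2.45 ± 0.32 log2 units, and Cyp2c54, Cyp2c37, Ces2a and Cyp2c50 by 2.02 ± 0.22, 1.91 ± 0.30, 1.28 ± 0.10 and 1.0 ± 0.20. In the 90-day vehicle livers Sult1e1, Nebl and Cyp2c65 lay at background (-0.02, 0.00 and -0.18 log2 units from it, and below it on 3, 4 and 4 of 5 arrays). The sizes of their changes are therefore not exact and may be too small. Cyp2c65 also rested on a single probe set, of the _s_at kind, and whether it binds related transcripts was not tested.

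In all, 23 genes were called at 90 days, 22 higher and 1 lower, and 727 had an unadjusted p under 0.05 where chance gives 803. The groups did not overlap for 21 of the 23, and for 171 of all genes (1.07%, where chance gives 0.794%). The 1 gene with a lower level, Rcan3, an inhibitor of calcineurin, fell by 0.48 ± 0.09 log2 units (adjusted p = 0.0378). Its other probe set differed by 0.07 in the opposite direction, and the mean of both gave an adjusted p of 0.814. The called genes also included Abcc4 (2.82-fold, 1.5 ± 0.27, adjusted p = 0.014), the pancreatic lipase-related gene Pnliprp1 (1.01 ± 0.17, adjusted p = 0.00772) and 4931406C07Rik (1.04 ± 0.14). The remaining ones were Gm10419 (2.41), 9030619P08Rik (1.98), Meig1 (1.67), Lrrc24 (1.39), Nsl1 (1.36) and Wdr18 (1.31). Without probe sets of the _x_at or _s_at kind Wdr18 gave 0.03 (adjusted p = 0.962). With the 2 arrays at the end of the first component left out 28 genes were called, 21 of the 23 among them, but not Nsl1 (0.0871) or Rcan3 (0.13).

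S100a8 had the largest mean change at 90 days, 77.8-fold (6.28 ± 1.13 log2 units, adjusted p = 0.0163), and rested on 4 of 5 mice. These 4 livers lay between 12.76 and 13.21, the fifth at 5.42, and the vehicle livers between 4.99 and 5.64. Its usual partner S100a9, which is made with it in neutrophils, differed by -0.01 ± 0.32. The call of S100a8 was lost without any of 8 arrays, all but vehicle replicate 1 and treated replicate 5 (adjusted p between 0.0521 and 0.0776), and in a fit of the 90-day groups alone (0.146). The same fit gave 0.146 for Abcc4 and 0.332 for Rcan3, and 0.146 for Nsl1.

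**Figure D2:**
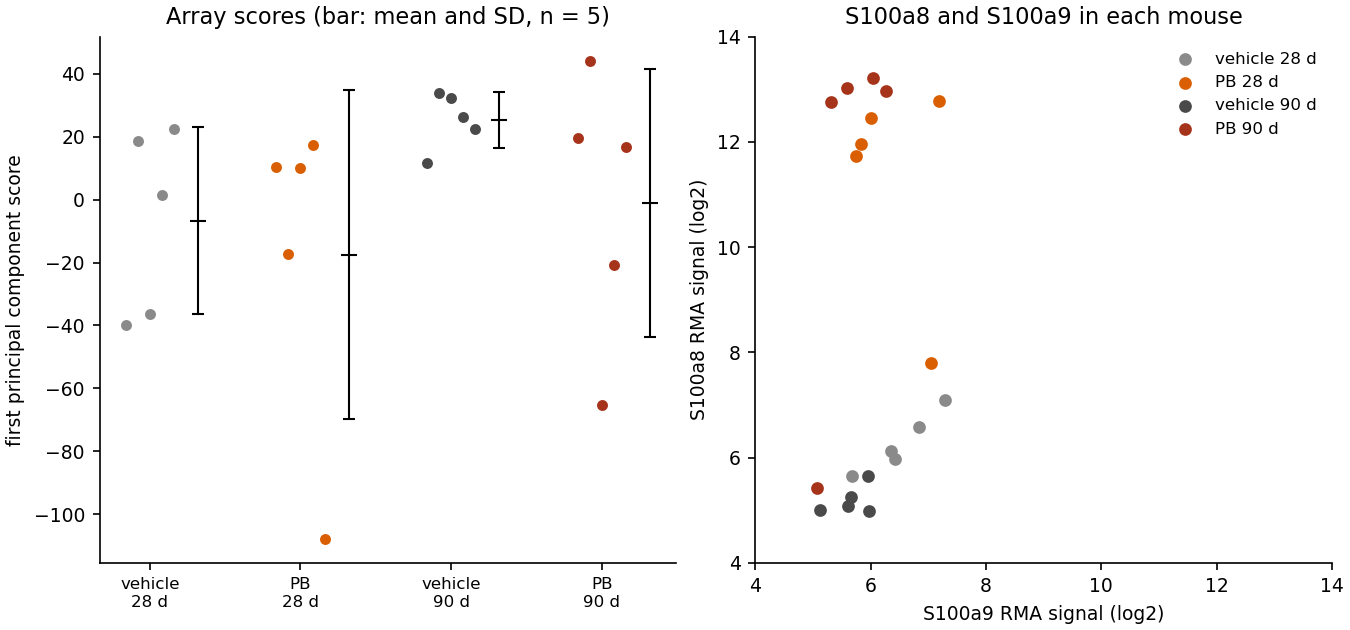
Left, score of each of the 20 arrays on the first principal component of 16054 genes (bars, mean and SD of 5), where treated replicate 5 of 28 days lies at -107.9 and treated replicate 3 of 90 days at -65.2. Right, log2 RMA signal of S100a8 (vertical) against S100a9 (horizontal) in each mouse; 8 treated livers lie between 11.73 and 13.21 for S100a8, with S100a9 in the range of the vehicle livers.

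The removal of single arrays touched other calls at 90 days as well. Cyp2c50 was no longer called without any of 8 arrays, all but vehicle replicate 2 and treated replicate 3 (adjusted p between 0.0729 and 0.202), nor after cyclic loess (0.0913) or without the intensity trend (0.0626). Rcan3 was lost without vehicle replicate 1, 2, 4 or 5 or treated replicate 1, 2 or 3 (between 0.0882 and 0.157). It was also lost without the trend (0.0821), with array weights (0.05) and on centring at the 75th percentile (0.719). Abcc4 was lost without vehicle replicate 4 or 5 or treated replicate 1 or 2 (between 0.0612 and 0.0708), and Serpinb1a without vehicle replicate 5 (0.0521) or treated replicate 1 (0.0533). Meig1 was lost without any of 8 arrays, all but vehicle replicate 1 and treated replicate 2 (between 0.0506 and 0.136), and Nsl1 without vehicle replicate 2, 3 or 4 or treated replicate 1, 3, 4 or 5 (between 0.0942 and 0.202). Cyp2b10, Cyp2c55, Cyp2c54, Cyp2c37, Ces2a, Sult1e1, Nebl, Cyp2b13, Cyp2c65, Orm3, 4931406C07Rik and Pnliprp1 were called at 90 days without each of the 10 arrays. With the replicate block, although the values did not show that the numbers pair mice, 10 of the 23 were not called: Pnliprp1 (0.0789), Serpinb1a (0.206), S100a8 (0.0929), Cyp2c50 (0.17), Rcan3 (0.181), Gm10419 (0.0572), 9030619P08Rik (0.0666), Lrrc24 (0.0811), Meig1 (0.206) and Nsl1 (0.423).

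The drug-metabolising groups at 90 days resembled those at 28 days in direction. Of the 36 genes of P450 enzymes and cytochrome b5 23 were positive, 7 were called over all genes and 10 adjusted over the list alone (adjusted p = 5.23e-08; adjusted p = 0.11 with an estimated correlation). The 7 were Cyp2b10, Cyp2b13, Cyp2c37, Cyp2c50, Cyp2c54, Cyp2c55 and Cyp2c65, and the other 29 were not called (adjusted p = 0.258). With the first component as a covariate beside an estimated correlation the list was called (adjusted p = 0.00887), as it was at 28 days (0.0353). Of the 44 genes of conjugation and epoxide hydrolysis 34 were positive (median 0.24, adjusted p = 1.41e-06; adjusted p = 0.113 with an estimated correlation). Sult1e1 was the 1 called over all genes, and 6 were called adjusted over the list alone, with Sult1c2 at 1.58 and Gstm3 at 1.51. Without Sult1e1 the other 43 still ranked higher (adjusted p = 4.87e-05, and 0.341 with an estimated correlation). The 41 esterases and reductases were not called as a list (adjusted p = 0.135), while Ces2a rose as the 1 member called over all genes and adjusted over the list alone.

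The tumour and fetal list ranked higher at 90 days with both forms of the test (adjusted p = 2.62e-06, and adjusted p = 0.00123 with an estimated correlation). It held 3 genes called over all genes, Cyp2b10, Cyp2c55 and Abcc4, and 6 adjusted over the list alone, where Prom1 gave 1.32 and Gstm3 1.51 and Tspan8 was the 1 lower. Without the 3 the list gave adjusted p = 0.0329, and 0.341 with an estimated correlation. Of 31 genes expressed more in females 23 were positive, with a median of 0.28 (adjusted p = 2.62e-06; adjusted p = 0.205 with an estimated correlation). Of them 2 were called over all genes, Sult1e1 and Cyp2b13, and 5 higher and 1 lower adjusted over the list alone. Without these 2 the other 29 still ranked higher (adjusted p = 0.00251, and 0.526 with an estimated correlation). The male-biased list was not called (median -0.04, adjusted p = 0.553).

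Several metabolic groups lay lower at 90 days, although in the first 3 below limma called 0 members over all genes or adjusted over the list alone and gave 2, 3 and 4 lower members at an unadjusted p under 0.05. Fatty acid oxidation and other targets of the receptor PPARα had 5 of 35 members positive, a median of -0.26 (adjusted p = 8.61e-08; adjusted p = 0.205 with an estimated correlation) and Acot1 at -0.85 and Cpt2 at -0.77. Endoplasmic reticulum stress and heat shock genes had 6 of 36 positive and a median of -0.41 (adjusted p = 9.94e-08; adjusted p = 0.438 with an estimated correlation), with Syvn1 at -1.46 and Creld2 at -1.14. Cholesterol genes had 4 of 26 positive and a median of -0.30 (adjusted p = 2.62e-06; adjusted p = 0.32 with an estimated correlation), with Sqle at -0.70. Nuclear receptors and their cofactors (median -0.28, adjusted p = 0.00108; 0.446 with an estimated correlation), pericentral genes (-0.26, 0.0122; 0.438) and clock genes (-0.32, 0.0234; 0.438) ranked lower as well. Each of these last 3 lists was lost without the 2 arrays at the end of the first component, with adjusted p of 0.108, 0.313 and 0.255. Plasma proteins (adjusted p = 0.0362; 0.592 with an estimated correlation) and bile acid genes (0.0426; 0.592) ranked lower by medians of -0.08 and -0.16, and turned to positive medians of 0.03 and 0.01 with the first component as a covariate.

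Of the markers of other tissues and cells at 90 days, the list of pancreatic and fat genes had 13 of 13 members positive (median 0.15, adjusted p = 0.000751; adjusted p = 0.438 with an estimated correlation) and held Pnliprp1, the 1 member called over all genes and adjusted over the list alone. Stellate cell genes ranked higher (median 0.11, adjusted p = 0.0119; adjusted p = 0.438 with an estimated correlation) and macrophage genes lower (-0.08, 0.0315; adjusted p = 0.592 with an estimated correlation). The macrophage median was -0.28 without the 2 arrays (adjusted p = 5.55e-06) and -0.34 with the first component as a covariate (8.3e-09; 0.38 with an estimated correlation as well), and the pancreatic and fat list was not called with the covariate (0.0615). Proliferation genes (median 0.11, adjusted p = 0.0377; 0.592 with an estimated correlation) and lymphocyte genes (0.16, 0.0433; 0.592) ranked higher, and neither did without the 2 arrays (0.243 and 0.233). The neutrophil list was not called (adjusted p = 0.0831), with S100a8 its 1 called member over all genes and adjusted over the list alone. In all 17 of 34 lists were called, 8 higher and 9 lower, 1 of them with an estimated correlation.

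**Figure D3:**
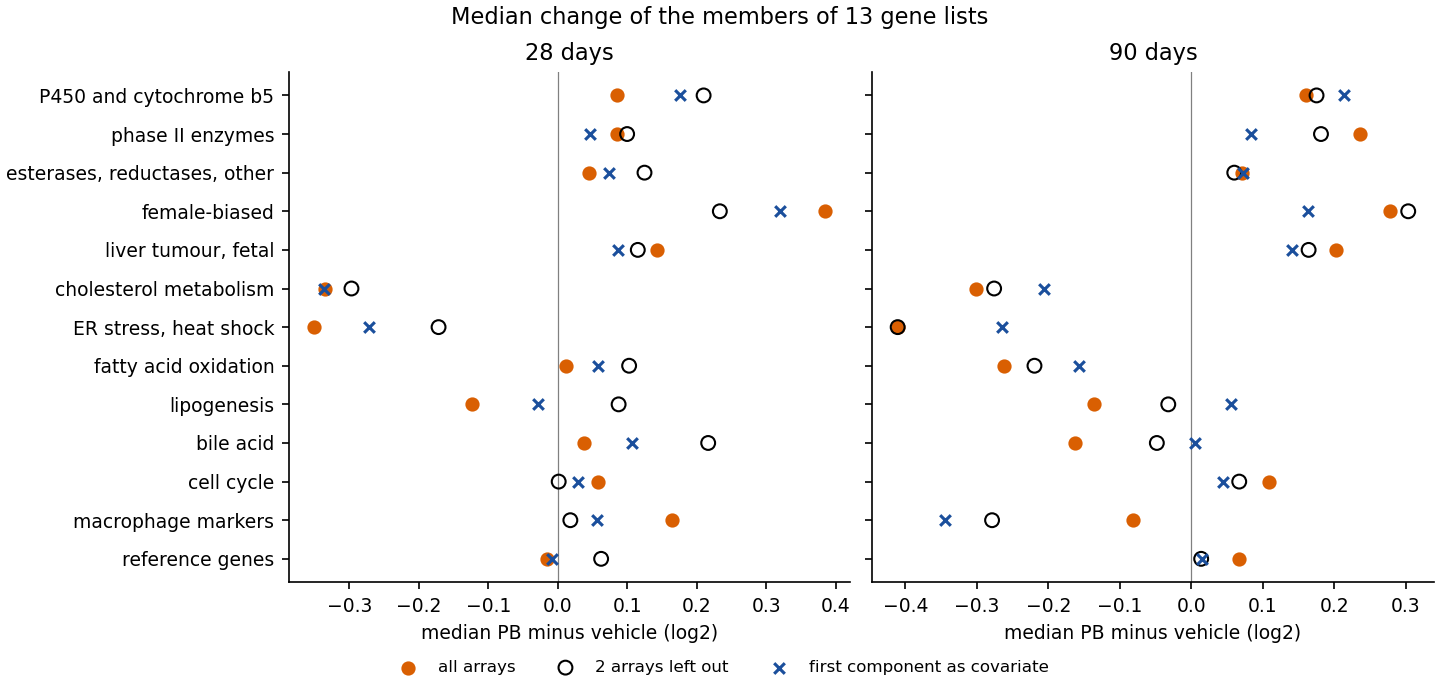
Median change (horizontal axis, PB minus vehicle, log2 units) of the tested members of 13 gene lists at 28 days (left) and 90 days (right), with all arrays, without the 2 arrays at the end of the first component, and with that component as a covariate. Cholesterol and stress genes stay below 0 in all 3 versions at both durations, at -0.33 and -0.35 with all arrays at 28 days, while lipogenesis crosses 0 at both durations and bile acid genes at 90 days.

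Lists called at neither duration were the acute-phase, biliary, endothelial, red cell, glucocorticoid, glucose, reference gene, male-biased, NRF2, p53, periportal, transporter and imprinted Dlk1-Dio3 genes. Their smallest adjusted p was 0.1 at 28 days, for the male-biased list, and 0.0695 at 90 days, for the glucose list. Within them Orm3 was called in the acute-phase list at 90 days, and Abcc4 in the transporter and NRF2 lists, as the 1 member each over all genes and adjusted over the list alone. Adjusted over the list alone, Abcc4 was also called in both lists at 28 days, and Prom1 in the biliary list at 90 days. The metallothioneins Mt1 and Mt2, counted with the acute-phase genes, were higher by 2.41 and 2.51 log2 units at 90 days without being called. Apoa4, a lipoprotein gene in the periportal and lipogenic lists, gave 1.10 at 90 days (adjusted p = 0.111) and was called in both lists adjusted over the list alone (0.00469 and 0.00631). At 90 days the heme and lipogenic lists were not called (adjusted p = 0.635 and 0.126).

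Some lists that were not called with all arrays were called after the 2 arrays at the end of the first component had been left out. Transporters ranked higher at 28 days (median 0.26 from -0.02, adjusted p = 5.62e-05), as did bile acid genes (0.22, 0.00022) and PPARα targets (0.10, 0.037). At 90 days the Dlk1-Dio3 (0.0118), esterase and reductase (0.0247) and endothelial lists (0.0458) ranked higher. With the first component as a covariate the transporters (0.00916) and bile acid genes (0.0363) at 28 days and the esterases and reductases at 90 days (0.00245) were called as well. With an estimated correlation beside the covariate none of these lists was called, and the smallest adjusted p was 0.366.

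Genes chosen in advance for their known link to phenobarbital or to liver growth were mostly not called. Cyp3a11, a drug-oxidising P450, was already near the top of the scale in vehicle livers (14.77 ± 0.04 at 28 days) and differed by 0.11 and 0.16 ± 0.06 log2 units at 28 and 90 days (adjusted p = 1 and 0.816). Alas1, the first enzyme of heme synthesis, differed by -1.49 ± 0.77 and -0.77 ± 0.77, with 95% intervals from -3.09 to 0.11 and from -2.37 to 0.83. The stress gene Gadd45b differed by 0.44 and 0.46 ± 0.22, and Nr1i3, which encodes the constitutive androstane receptor itself, by 0.00 and 0.12 ± 0.27. The imprinted RNA Meg3 differed by 0.47 and 0.92 ± 0.45, and its 11 probe sets were all higher at both durations without any call. Mki67, a marker of dividing cells, gave 0.35 and 0.11 ± 0.12, Ccnd1 -0.06 and -0.27 ± 0.15, Glul -0.35 and -0.27 ± 0.24, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -0.94 and -1.07 ± 0.49. The direction of Nr1i3 turned under 3 alternatives at 28 days and 1 at 90 days.

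The effect of phenobarbital was next compared between durations. All 8 genes called at 28 days were also called at 90 days in the same direction, where independent lists would share 0.0110 genes. Sult1e1 had the largest evidence for a greater effect at 90 days, 2.81 ± 0.51 log2 units more than at 28 days (95% interval 1.75 to 3.87), but with an unadjusted p of 2.1e-05 by limma it did not pass over all genes (adjusted p = 0.337). In limma 0 genes were called for the difference, and 221 had an unadjusted p under 0.05. Among the 23 genes called at 90 days, 19 had the larger effect at 90 days, and 2 passed when adjusted over the list alone, Sult1e1 (0.000483) and Lrrc24 (1.09 ± 0.31, 0.0225); these 23 were picked for their effect at 90 days, which favours that direction. Next by p over all genes were 4833438C02Rik (0.67 ± 0.16) and Nap1l3 (1.01 ± 0.26). For Nap1l3 this was not a greater rise at 90 days. Its change was -0.81 ± 0.18 at 28 days and 0.20 ± 0.18 at 90 days, neither called. The 28-day vehicle livers stood apart with a mean of 5.40, against 4.59 in 90-day vehicle livers and 4.59 and 4.79 in treated ones. In vehicle livers 4833438C02Rik lay 0.11 log2 units above background at 28 days and 0.06 below it at 90 days, so the size of its difference is not exact.

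Cyp2b10 and Cyp2c55 did not differ detectably between durations, with differences of 0.99 (95% interval -0.85 to 2.82) and -0.17 (-1.05 to 0.70). Among the lists, PPARα targets had a more negative effect at 90 days (median -0.25, 3 of 35 positive, adjusted p = 1.49e-08; adjusted p = 0.741 with an estimated correlation), and so did macrophage markers (median -0.32, adjusted p = 0.00446; adjusted p = 0.972 with an estimated correlation). In both lists limma called 0 members over all genes and 0 adjusted over the list alone, and 0 had an unadjusted p under 0.05. PPARα targets also ranked higher in 90-day than in 28-day vehicle livers, which are the controls in this difference. Their more negative effect at 90 days thus cannot be ascribed to the treated livers alone. Across 16054 genes, which are not independent replicates, the changes at the 2 durations had a Pearson correlation of 0.576 and a Spearman correlation of 0.409. Without treated replicate 5 of 28 days the Pearson value was 0.0546, and without both arrays at the end of the first component 0.331, so this value rested on single arrays. Leaving out both arrays added 3 lists to the difference, bile acid genes (0.000839) and transporters (0.011) with a more negative effect at 90 days and pancreatic and fat genes (0.0173) with a more positive one. With all arrays none of these 3 was called, nor with an estimated correlation (adjusted p = 0.972 with an estimated correlation for each).

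**Figure D4:**
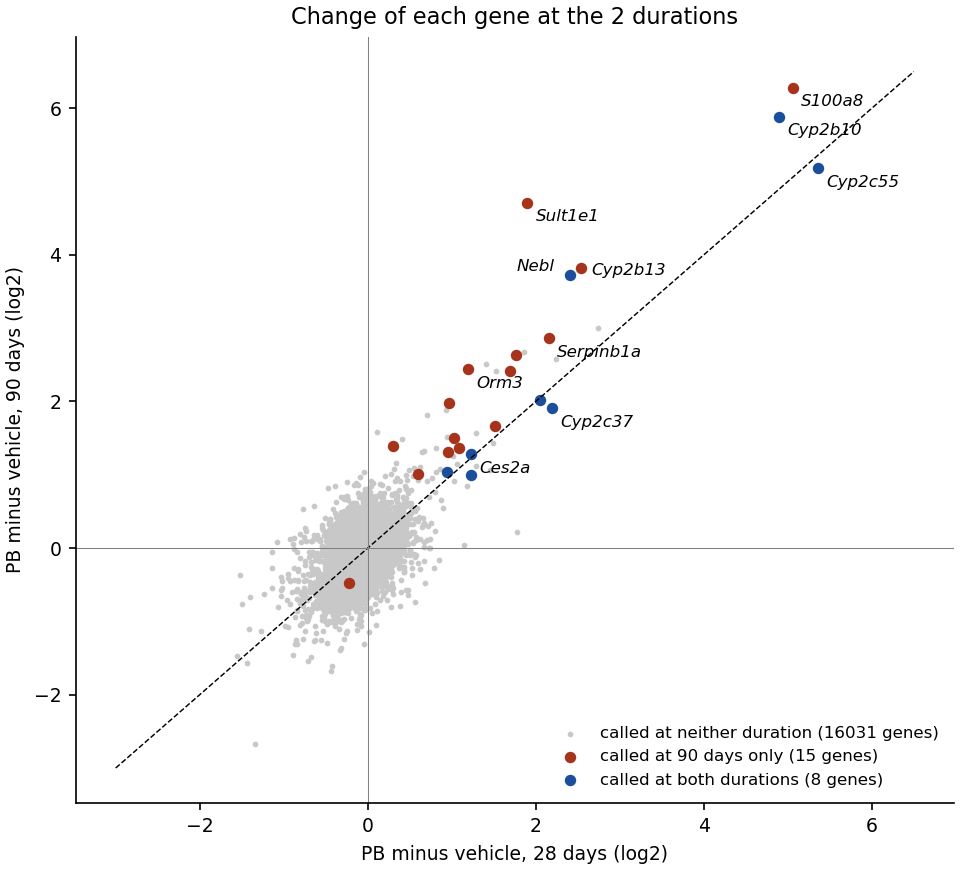
Change of each of 16054 genes under phenobarbital at 28 days (horizontal axis) and at 90 days (vertical axis), in log2 units of PB minus vehicle; the dashed line marks equal change, and colours mark genes with an adjusted p under 0.05 at both durations (8), at 90 days but not at 28 (15) or at neither. Sult1e1, at 1.90 and 4.71, lies farthest above the line among the called genes.

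Vehicle livers at 90 and 28 days served as the background for age and occasion of sampling. Limma called 0 of 16054 genes, with a smallest adjusted p of 0.636 and 913 genes at an unadjusted p under 0.05. A fit of the 2 vehicle groups alone gave 2403 such genes, where 803 would be expected by chance. Leaving out the 2 arrays at the end of the first component gave 2814, and that component as a covariate 560. A shift between the vehicle groups spread over many genes is thus not excluded. No overlap between the groups was seen for 374 genes (2.33%), where chance gives 0.794%. Sult1e1 differed by -0.13 ± 0.36, Cyp2b10 by -0.22 ± 0.62 and Cyp2c55 by 0.30 ± 0.30 log2 units. Of the lists, 12 were called, 10 higher and 2 lower at 90 days, and all 12 were lost with an estimated correlation (adjusted p between 0.591 and 0.842). Higher were cholesterol genes (median 0.28, adjusted p = 4.66e-06), PPARα targets (0.24, 2.1e-05), lipogenesis (0.41, 0.000837), transporters (0.33, 0.000837), nuclear receptors (0.26, 0.00167) and glucose genes (0.16, 0.00853). Bile acid genes (0.0232), plasma proteins (0.0271), esterases and reductases (0.0317) and clock genes (0.0463) were also higher. Macrophage markers (-0.43, 2.1e-05) and pancreatic and fat genes (-0.20, 0.00185) were lower, and limma called 0 of the 338 list members tested over all genes or adjusted over the list alone, with 36 at an unadjusted p under 0.05.

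Cholesterol, PPARα, nuclear receptor, clock, plasma protein and bile acid genes ranked lower under phenobarbital at 90 days. The same lists ranked higher in 90-day than in 28-day vehicle livers. The 90-day vehicle livers were the controls in the first comparison and entered the second with the opposite sign. Opposite directions can therefore arise from these shared arrays alone, and the 2 results are not independent. The pancreatic and fat genes showed the reverse, with 13 of 13 higher under phenobarbital at 90 days and 0 of 13 higher in 90-day than in 28-day vehicle livers. The shared arrays can give this contrast too. Centring each array on its 75th percentile shifted the median of all genes in the comparison of the vehicle groups by -0.119 log2 units. Of the 12 lists, 3 were called both without the 2 arrays and with the first component as a covariate: cholesterol genes, PPARα targets and macrophage markers. The covariate added the acute-phase (0.02) and glucocorticoid genes (0.0217), both lower at 90 days, which were lost with an estimated correlation beside the covariate (0.91 and 0.865). Leaving out the 2 arrays added the NRF2 list (0.0302), which was higher, and which gave 0.591 with all arrays and an estimated correlation.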

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

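The splits of the samples and the cyclic loess test were planned before their results were seen; the tests on genomic span, ribosomal and Malat1 levels, treatment, S100a8 and Sult1e1 were chosen after. For 30 values, named genes and array measures, each of the 4 groups was checked for a mouse far from the other 4. Chance alone would mark about 1 in 20 of these checks, and 18 of 120 (15%) were marked. The checks shared the same arrays and were not independent, so this share does not measure an excess over chance. Replicate 5 of PB at 28 days accounts for 7 of the 18.

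The first pattern is 2 treated arrays apart on the first component, PB replicate 5 at 28 days at -107.9, with the smallest array SD of its group (2.073), and PB replicate 3 at 90 days. Compression of signal is argued against by cyclic loess, after which the higher of the 2 scores was still -65.1 against -37.84 for the lowest of the others. Loss of long RNA, as in partly degraded samples, stays open: level fell with genomic span on these arrays, with rank correlations of -0.2043 and -0.2389 against -0.1908 for the lowest of the other 18, the short ribosomal protein transcripts were highest (median deviations of 0.540 and 0.506, next 0.418) and the long RNA Malat1 lowest (9.45 and 10.51, next 11.79). Against it, the longest 10% of genes had median deviations of only -0.031 and -0.024, while vehicle replicate 3 at 28 days had -0.081; span is a proxy for RNA length, and control probe sets were not used here. A part of the treatment cannot be told apart from chance, because the 2 arrays were picked for lying below all vehicle arrays, which left 0 of the other 8 PB arrays there, and it stays open whether the livers themselves differed.

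The second pattern is S100a8, far higher in 8 of 10 treated livers without S100a9, and low in PB replicate 5 at 28 days (7.796) and PB replicate 5 at 90 days (5.418). Neutrophils in the liver would raise S100a9 too, and its change at 90 days had an upper 95% bound of 0.6561, against 3.14 for 1/2 of the change of S100a8. At 28 days that bound was 0.51, beside a change of S100a8 of 5.06. The 12 other neutrophil genes nevertheless ranked higher at 28 days by camera (adjusted p = 0.0079, and 0.302 with an estimated correlation). Their changes were small, with a median of 0.18 and a highest value of 0.32. The shift along the first component does not account for the low value at 90 days, where the array scored 16.79, nor does an untreated mouse, as its Cyp2b10 was 12.23 against at most 7.779 in vehicle livers. For the array at 28 days, with its score of -107.9, that shift and biology cannot be told apart, and RNA quality was not measured for either. The single probe set may also bind another induced transcript, which was not tested, so an induction of S100a8 outside neutrophils is no more than a hypothesis.

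The third pattern is Sult1e1, picked for the smallest p of 16054 genes, whose effect was larger at 90 days by 2.809 log2 units without passing over all genes (adjusted p = 0.337). With the first component as a covariate the difference was 2.72 ± 0.48, so that variation along this component does not account for it, while RNA quality itself was not measured. The measured difference lay mainly in the PB livers. Between the 2 durations they differed by 2.68 ± 0.36, with a lower 95% bound of 1.928 against 1.40 for 1/2 of the difference. This outcome was nearly fixed, because vehicle livers lay at background at both durations and could hardly fall further. It is thus no separate test of a lower level in the older vehicle livers. A batch of arrays that follows duration cannot be told apart from the larger effect at 90 days. Vehicle livers lay only 0.01383 above the background percentile and could show no shift. A further rise with longer dosing is thus one hypothesis, beside age, batch and RNA quality.

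Other mice far from their group were, among vehicle livers, replicate 1 at 90 days for Cyp2b10 (7.763, high), replicate 4 at 90 days for Nebl (4.382, high), replicate 3 at 28 days for Cyp2c50 (11.81, low), replicate 5 at 28 days for Serpinb1a (3.993, low) and Orm3 (8.276, high), and replicate 1 at 28 days for 4833438C02Rik (4.402, high). Among treated livers, replicate 5 at 28 days was low for Cyp2c37 (7.338), Cyp2c50 (12.87), Ces2a (13.42) and Glul (10.82), replicate 3 at 90 days was low for Cyp2b10 (10.54) and Cyp2c54 (13.28), and replicate 5 at 90 days was low for Nebl (6.877) and high for Ccnd1 (7.497). The effect on Lrrc24 was larger at 90 days by 1.088 log2 units among the 23 genes tested. Among all 45037 probe sets, those without a single gene symbol gave 1 call at 28 days and 1 at 90 days, the same probe set in both cases, which rose by 1.82 ± 0.28 (adjusted p = 0.00861) and 1.98 ± 0.28 log2 units (adjusted p = 0.00185).

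Of 100 splits of the 10 arrays at 28 days, the real one included, 2 gave at least 8 genes and 2 at least 7 with a change of 1 log2 unit. Such counts were thus rare among the splits but not absent, since the other split gave 1521 and 398 genes. That split had the widest gap on the first component of all 100 (55.7, against 10.8 for the real one), which points to a structure of the samples along this component. The 12 lists at 28 days were reached by 57 of 100 splits (highest other 19), so chance cannot be excluded for their number. At 90 days 1 of 100 splits, the real one, gave 23 genes and 22 with a change of 1 log2 unit (highest other 1 for both). No other split drawn came near these counts of genes. At least 17 lists were called in 4 of 100 splits, and another split called 18. The number of lists at 90 days thus lay inside the range of the other splits, and chance is not excluded for it. For the difference between durations 96 of 100 splits gave at least 2 lists (highest other 21), and in the vehicle groups 25 of 100 gave at least 12 (highest other 18), so chance cannot be excluded for these numbers of lists. The counts of 0 genes in these 2 comparisons cannot be tested in this way, since any split gives at least 0 (100 of 100). The highest other counts were 3 genes in the vehicle groups and 5212 for the difference, the latter again in the split with the widest gap (47.0 against 7.81).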

How the results depend on the processing

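Removal of the 2 arrays together, the first component as a covariate and lists without singly called genes were chosen after the data were seen. Over the alternatives without single-array removals, 660 values of named genes kept direction and side of the threshold, 21 lost the call, 8 gained it and 5 turned; for single-array removals these were 574, 36, 5 and 5. For list calls, 424 were kept and 176 lost, and over single-array removals 386 and 64.

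At 28 days the 8 genes became 4 in a fit of only the groups compared, 17 with array weights and 17 with the first component as a covariate. Those changed by at least 1 log2 unit became 4, 12 and 12 from 7, and 11 without the 2 arrays. Removing 1 array gave 6 to 10 genes (5 to 10 by at least 1 log2 unit). At 90 days the 23 genes became 21 in a fit of only the groups compared. They became 15 with the replicate block (14 from 22 by at least 1 log2 unit), and 17 to 23 (15 to 22) without 1 array. The cause of these changes was not tested. Counts for the difference and the vehicle groups were 0 in limma under each alternative, and the correlation lay between 0.0546 and 0.694 without 1 array.

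Rcan3 at 28 days turned to 0.053 with the mean of its probe sets. Nr1i3 at 28 days turned to -0.18 with array weights, -0.16 without the 2 arrays and -0.090 with the first component, ranging from -0.24 to 0.14 without 1 array, and at 90 days to -0.10 with the first component. Ccnd1 at 28 days ranged from -0.13 to 0.012. The cause was not tested.

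The values did not show that the replicate numbers paired the mice, and the labels do not say. Same-numbered mice had deviations correlated between -0.60 and 0.26 at 28 days and between -0.23 and 0.36 at 90 days. At each duration 1 of 5 correlated best with its own number. Between the vehicle groups the correlations lay between -0.21 and 0.45, and 2 of 5 were best with their own number. With the replicate block 7 genes were called at 28 days. Signal near background limits Sult1e1, Nebl, Cyp2c65, Pnliprp1 and 4833438C02Rik in vehicle livers, where RMA compresses differences. A fit of only the groups compared could not be run for the difference, which needs all 4 groups.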

Other observations

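Some genes varied between mice of the same group far more than the median gene, whose pooled within-group SD was 0.273 log2 units, and the 10 most variable ones were looked up after the data were seen. Moxd1, a gene expressed more in male livers, had the largest pooled SD, 2.26, and ranged from 4.24 to 11.8, with SDs of 3.30 and 2.70 in the vehicle and treated groups of 90 days. The acute-phase genes Lcn2 and Saa2 had pooled SDs of 2.10 and 2.02. Saa2 had an SD of 2.90 and 2.71 in the vehicle groups of 28 and 90 days, and of 0.465 and 0.572 in the treated groups. Dbp, a clock output gene whose level follows the hour, ranged from 4.78 to 12.2 (pooled SD 2.04). Hsd17b13, a lipid droplet enzyme of hepatocytes, had SDs of 0.586 and 0.667 at 28 days and of 2.45 and 2.57 at 90 days in vehicle and treated livers. The others were Cyp4a14, S100a8, Dmbt1, Gdpd3 and the metallothionein Mt2, and the correlation of these 10 genes with the first component over the 20 arrays lay between -0.306 and 0.370. No test of these spreads between groups was made.

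Cyp2b13, Cyp2b9 and Cyp2b10 are close relatives, and their probe sets did not follow Cyp2b10 alone. Over the 10 treated livers the difference between Cyp2b13 and Cyp2b10 had an SD of 0.739, and that between Cyp2b9 and Cyp2b10 of 0.787, whereas the other 2 probe sets of Cyp2b10 differed from the first with SDs of 0.0636 and 0.112. Cyp2b9, expressed mainly in females, was higher by 2.75 log2 units at 28 days and by 3.01 at 90 days without being called over all genes.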
